A study of Mus musculus with 9 samples.

How the data were processed

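RNA-seq was made from 9 mouse samples, in 3 groups of 3: fresh E11.5 lung, control explants and EPZ5676 explants after 72 h of culture. Per the labels' protocols, total RNA was extracted with TRIzol, 1 ug was used, and libraries were made with the Vazyme VAHTS Universal V8 kit. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart. The submitters' processing notes name RSEM, Bowtie2 and the build mm10, with no versions or roles. The authors deposited a table of expected counts per gene, which are estimated and need not be whole; 12.5% to 15.3% of the values were not whole. The authors also deposited a table of TPM, an abundance scaled by transcript length and depth, in which each library summed to between 998977 and 999233. Expected counts divide reads between genes that share sequence, so values of paralogs and pseudogenes are estimates. Both tables held 55286 genes with Ensembl identifiers and symbols, and 100% of the pairs matched GENCODE M21 (GRCm38, the same assembly as mm10), from which positions were taken.

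Expected counts were rounded to whole numbers. Libraries held 6509563 to 9861452 counts. Low counts limit what can be seen, and intervals and floors cover counting error only, since reads are not independent molecules. Genes were filtered with filterByExpr (minimum count 10), which left 15158, and scaled by TMM. All 9 libraries entered a single fit by group, with 6 residual degrees of freedom, and each comparison was tested two-sided with edgeR 4.0.16 (robust quasi-likelihood F test, legacy method) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change was derived from its F statistic. Log2 CPM used a prior count of 2. Fold changes come from counts and TPM are given as deposited, so they need not match exactly.

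Before the data were examined, 51 gene lists with 1026 members were fixed for cell types, signalling, cell cycle, stress and metabolism; 1025 members were in the tables. Lists were tested with camera in limma 3.58.1 on voom weights with a preset correlation of 0.01, adjusted over the 51 lists. None of the calls made this way held when the correlation was estimated per list, in either comparison tested. A list was called as a whole relative to other genes, while counts adjusted over the list alone refer to single genes.

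Genes were named by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls past the threshold without overlap between groups, with a mean TPM of at least 1 in the higher group (3 each way for EPZ5676 against fresh lung), leaving out predicted and clone names. It added 12 anchor genes and, from each list described, up to 4 passed members with the largest change or, where none passed, 2 with the smallest p. The text gives a selection of these, and a few genes the rule takes are not reported here. Any gene outside the rule is said to have been chosen after its values were seen.

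Libraries were compared before averaging: counts of replicates differed by more than sampling noise in every pair (chi-square per degree of freedom 2.63 to 31.0), so none was counted as a duplicate. The tools were tested on simulated data for EPZ5676 against control with 15158 genes. There edgeR recovered 20.9% of 1.5-fold, 56.7% of 2-fold and 89.4% of 4-fold changes with 7.26% false calls, and DESeq2 29.9%, 65.7% and 89.4% with 21.0% false calls. Limma recovered 20.9%, 56.7% and 90.9% with 6.50% false calls. These data were drawn with a single spread per gene from all 9 libraries. The biological coefficient of variation was 10.9% in fresh lung, against 24.5% and 18.8% in the control and EPZ5676 groups compared. Genes were drawn independently, and changes were planted only above a minimum expression level. The recovered shares may therefore be too high for the real comparison.

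Alternatives fixed in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter or a filter of 50 counts in 3 libraries, a fit to the 6 libraries of a comparison, the replicate number as a block, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), a 2-fold limit, fry and an estimated correlation for lists, and leaving out each library. A newer quasi-likelihood method of edgeR and the Xist level as a covariate were added after seeing the data. Figures were drawn with matplotlib 3.10.9.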

Results

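RNA from mouse embryonic lungs was sequenced in 3 groups of 3 libraries. The first group held lungs taken at E11.5, the embryonic day when the airway buds have begun to branch. The other 2 groups were explants of E11.5 lung kept in culture for 72 h, either as untreated controls or with EPZ5676. EPZ5676, also called pinometostat, is a small molecule that blocks DOT1L, the enzyme that methylates lysine 79 of histone H3. The libraries held 6509563 to 9861452 counts each. The labels do not say that libraries of a group came from separate embryos or cultures, so the p-values below measure the spread between these libraries, which may be partly technical. Values are deposited TPM as mean ± SD over 3 libraries, and log2 fold changes are given ± SE.

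The fresh lungs stood far from both cultured groups. The first principal component held 60.2% of the variance and separated the 3 fresh libraries from the 6 cultured ones. The correlation of log2 CPM within a group was 0.975 to 0.986 for fresh lung, 0.944 to 0.966 for control explants and 0.960 to 0.971 for EPZ5676 explants. Between control and EPZ5676 libraries it was 0.946 to 0.973, so by this measure the cultured libraries did not group by treatment. The biological coefficient of variation was 10.9% in fresh lung, 24.5% in controls and 18.8% with EPZ5676. Xist, which is transcribed in female cells, was at 281 and 278 TPM in Control 1 and Control 2 and at 210 TPM in EPZ5676 2. It was at 0.25 TPM in Control 3, 0.58 TPM in EPZ5676 1 and 0.77 TPM in EPZ5676 3, where the Y-linked gene Ddx3y was at 45.4, 55.7 and 49.9 TPM. The cultured groups thus differed in the number of Xist-expressing libraries. Of the fresh libraries, E11.5 1 had Xist at 284 TPM with Ddx3y at 0, while E11.5 2 and E11.5 3 held both transcripts. These 2 may be pools of embryos, which the labels do not say, so the spread of fresh lung need not be one between embryos. Control 1 stood apart in transcripts of other tissues. Its list mean was 4.87 log2 CPM for liver genes (1.05 and 1.00 in Control 2 and Control 3, 1.40 to 1.96 with EPZ5676), 3.59 for heart muscle genes (1.43 and 2.27, and 2.00 to 2.27) and 5.64 for cartilage genes (4.37 and 3.82, and 4.18 to 5.08).

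**Figure D1:**
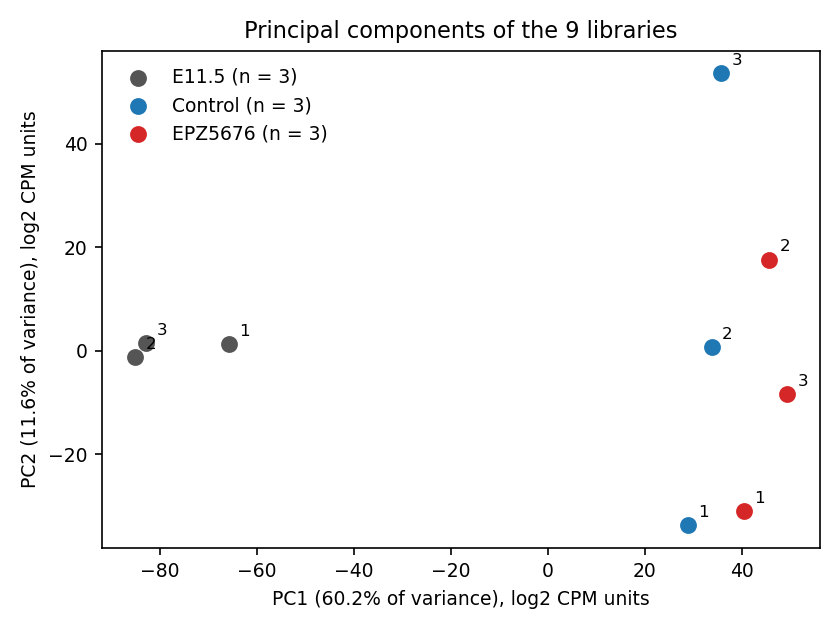
Principal components of log2 CPM for the 9 libraries, with 1 point per library, coloured by group and numbered by replicate. The first axis (60.2% of the variance) separates fresh lung from both cultured groups, and Control 3 has the highest value on the second axis (11.6% of the variance).

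The comparison of EPZ5676 with control explants addressed the study's question of what DOT1L inhibition does to the growing lung. Transcripts of ciliated and secretory airway cells lay above control in the treated explants. Deup1, from the ciliated cell list, was at 16.6 ± 13.9 TPM with EPZ5676 and 0.79 ± 0.56 TPM in controls (log2 fold change 4.43 ± 0.69, n = 3 per group, edgeR adjusted p = 0.131). Scgb3a2, a protein secreted by airway club cells, was at 369 ± 204 against 43.2 ± 18.2 TPM (log2 fold change 3.04 ± 0.53, edgeR adjusted p = 0.197). Genes of cholesterol synthesis and of the HOX and MEIS families lay below control, such as Cyp51, a sterol demethylase, at 60.7 ± 12.9 against 87.8 ± 2.0 TPM (log2 fold change -0.57 ± 0.13, edgeR adjusted p = 0.279). No single gene passed the adjusted threshold of 0.05 with edgeR, while DESeq2 called 104.

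Of 15158 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower, with a lowest adjusted p of 0.131. At an unadjusted p under 0.05 there were 627 higher and 425 lower genes, 1052 in all, where chance alone gives 757.9. This fit took its spread from all 9 libraries, of which fresh lung varied least. A fit to only the 6 libraries compared had 762 of 14643 genes under 0.05, close to the share chance gives. Its lowest adjusted p was 0.459, so most of the excess was gone without the fresh libraries. DESeq2 called 88 higher and 16 lower, limma-trend called 0 on log2(TPM + 1) and 1 on log2(TPM + 0.1), and edgeR without a filter on low counts called 67 and 9. With EPZ5676 2 left out edgeR called 26 higher and 0 lower, and 24 of these 26 were among the DESeq2 calls. Deup1 (DESeq2 adjusted p = 1.4e-08), Scgb3a2 (0.00386), Ctsh (4.0e-04) and Ccdc39 (7.6e-04) passed with DESeq2, and Deup1 and Scgb3a2 also passed with edgeR without EPZ5676 2 (adjusted p = 0.0328 and 0.0465). In its group EPZ5676 2 had the lowest mean of the ciliated cell list and the only high Xist. Without EPZ5676 2 the median log2 fold change of that list was 2.52, against 1.90 over all libraries, but it covered 16 members instead of 14. The median also rose, to 2.34, 2.28 and 2.12, without Control 1, 2 and 3, again over 16 members. How much of these rises came from the added members was not tested. Leaving EPZ5676 2 out also made the groups less alike in Xist. The 3 libraries of a group all lay on 1 side of the other group's for 10.2% of genes, against 10% by chance.

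Of the lists that passed camera, the ciliated cell list had the largest median change. Of its 14 tested members 13 were above control, and 11 were higher when adjusted over the list alone, against 0 over all genes tested. The median log2 fold change was 1.90, and the list passed its camera test (adjusted p = 6.6e-12) but not with an estimated correlation (adjusted p = 0.378 with an estimated correlation). Ccdc39, which helps assemble the motor arms of cilia, was at 16.5 ± 7.0 TPM against 5.0 ± 0.81 TPM in controls (log2 fold change 1.75 ± 0.32). The list mean was 3.60, 3.07 and 4.71 log2 CPM in the EPZ5676 libraries and 2.07, 2.16 and 1.70 log2 CPM in the control libraries. These are given in the order of replicates 1, 2 and 3, and Xist was high in EPZ5676 2 and in Control 1 and Control 2.

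Other epithelial lists went the same way with smaller sizes. All 11 tested members of the proximal airway list were above control, with 3 higher when adjusted over the list alone and a median log2 fold change of 0.82 (camera adjusted p = 1.0e-07, and adjusted p = 0.313 with an estimated correlation). Muc16, a membrane mucin, had a log2 fold change of 1.31 ± 0.34. Of 28 pan-epithelial genes 25 were above control, 3 when adjusted over the list alone, with a median log2 fold change of 0.29 (camera adjusted p = 1.0e-07, and adjusted p = 0.498 with an estimated correlation). Krt19, a keratin of simple epithelia, was at 123 ± 35 against 58.6 ± 18.5 TPM, and the epithelial transcription factor Ehf at 10.8 ± 2.2 against 3.11 ± 1.72 TPM. All 13 members of the alveolar type 2 list were above control, with 3 higher when adjusted over the list alone and a median of 0.70 (camera adjusted p = 1.4e-06, and adjusted p = 0.313 with an estimated correlation). Ctsh, a protease that trims surfactant protein precursors, was at 110 ± 11 against 57.4 ± 7.6 TPM, and Sftpa1, a surfactant protein, at 25.4 ± 5.4 against 12.2 ± 4.0 TPM. All 14 members of the alveolar type 1 list were above control, with 2 higher when adjusted over the list alone and a median of 0.34 (camera adjusted p = 2.8e-06, and adjusted p = 0.373 with an estimated correlation). Emp2 had a log2 fold change of 0.73 ± 0.20 and Krt7 of 0.50 ± 0.14. The mesothelium list had 11 of 13 members above control, with 2 higher when adjusted over the list alone and a median of 0.80 (camera adjusted p = 2.3e-06, and adjusted p = 0.373 with an estimated correlation). Its smallest p-values belonged to Krt19 and Muc16, which other epithelial lists also hold.

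These lists kept their camera calls with each library of the comparison left out, while several medians moved. Keeping a call says little by itself, since other splits of the same 6 libraries gave 9 to 21 called lists. The pan-epithelial list mean was 4.72 log2 CPM in Control 3, against 5.27 in both other controls and 5.48, 5.25 and 5.69 log2 CPM in EPZ5676 1, 2 and 3. The median of this list was 0.13 without Control 3, 0.19 without EPZ5676 3 and 0.44 without EPZ5676 2. The alveolar type 1 list mean was 4.31, 4.67 and 5.23 log2 CPM in Control 1, 2 and 3, so Control 3 lay inside the range of the EPZ5676 libraries (4.96 to 5.26 log2 CPM). The median of this list was 0.14 without Control 1 (camera adjusted p = 0.0314) and 0.70 without Control 3. The proximal airway median was 1.28 without Control 1, and without EPZ5676 2 the alveolar type 2 median was 0.41 and the mesothelium median 0.49.

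The lung epithelial identity list, made of transcription factors and signals that specify the lung lining, lay on the other side. Of its 13 members 11 were below control, 0 when adjusted over the list alone, with a median log2 fold change of -0.15 (camera adjusted p = 0.0295, and adjusted p = 0.516 with an estimated correlation). That call was lost in 4 of the 6 fits that left out a library, with a highest adjusted p of 0.213 without EPZ5676 2. The median was -0.090 without Control 1, -0.25 without Control 3, -0.26 without EPZ5676 1 and -0.082 without EPZ5676 2.

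Several lists of mesenchymal and patterning genes lay below control. Of 22 HOX, MEIS and PBX genes 19 were lower in mean, 5 when adjusted over the list alone, with a median log2 fold change of -0.23 (camera adjusted p = 2.8e-06, and adjusted p = 0.373 with an estimated correlation). Meis1, a partner of HOX proteins, was at 58.6 ± 7.5 against 80.8 ± 6.4 TPM, and Hoxa4 at 8.57 ± 3.25 against 16.4 ± 3.8 TPM. The median was -0.43 without Control 1 and -0.45 without EPZ5676 2. Of 25 mesenchyme and fibroblast genes 18 were below control, 2 when adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.0119, and adjusted p = 0.609 with an estimated correlation). These 2 were Tbx5, at 41.7 ± 5.7 against 58.2 ± 3.3 TPM, and Tbx4, at 49.1 ± 7.3 against 65.6 ± 1.1 TPM, both transcription factors of lung mesenchyme. This list's call was lost without Control 1, the library with more liver, heart muscle and cartilage transcripts, and without Control 3 or EPZ5676 3 (highest adjusted p 0.311). Its median was -0.25 without Control 2, -0.0062 without Control 3 and -0.088 without EPZ5676 3. Of 14 Hedgehog genes 12 were below control, with a median of -0.23 (camera adjusted p = 7.1e-04, and adjusted p = 0.498 with an estimated correlation). Gli2 and Foxf1, which act downstream of Hedgehog in the mesenchyme, had log2 fold changes of -0.43 ± 0.16 and -0.50 ± 0.19. The Hedgehog median was -0.41 without EPZ5676 1 and -0.14 without EPZ5676 2. Of 18 neural crest, glia and neuron genes 17 were below control, with a median of -0.79 (camera adjusted p = 0.00107, and adjusted p = 0.669 with an estimated correlation), and the call was lost without Control 3 (median -0.089, adjusted p = 0.382). Elavl4, a neuronal RNA-binding protein, was at 2.90 ± 0.84 against 4.84 ± 2.73 TPM.

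In metabolism, 22 of 25 cholesterol synthesis genes were below control, 1 when adjusted over the list alone, with a median log2 fold change of -0.28 (camera adjusted p = 2.9e-08, and adjusted p = 0.481 with an estimated correlation). Msmo1, a sterol oxidase of the pathway, was at 92.5 ± 20.1 against 145 ± 11 TPM. The list mean was 6.34 log2 CPM in EPZ5676 1, inside the range of the controls, and 5.72 and 6.12 log2 CPM in EPZ5676 2 and EPZ5676 3. The median was -0.47 without EPZ5676 1 and -0.12 without EPZ5676 2. Of 30 hypoxia and glycolysis genes 24 were above control, 0 when adjusted over the list alone, with a median of 0.18 (camera adjusted p = 2.4e-05, and adjusted p = 0.378 with an estimated correlation). Ldha, lactate dehydrogenase, was at 344 ± 41 against 251 ± 27 TPM. Car9, a carbonic anhydrase, had a log2 fold change of 1.43 ± 0.44 from counts, while its TPM were close, at 3.06 ± 1.43 against 2.78 ± 1.39. The macrophage and leukocyte list had 17 of 22 members above control, 0 when adjusted over the list alone, with a median of 0.18 (camera adjusted p = 7.2e-04, and adjusted p = 0.498 with an estimated correlation). C1qb, a complement component, was at 42.3 ± 10.6 against 20.7 ± 10.3 TPM. The median of this list was 0.30 without Control 1, 0.28 without EPZ5676 2 and 0.11 without EPZ5676 3.

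The study's title concerns proliferation of the epithelium, and the cell cycle lists went in different directions. Of 42 genes of G1/S and DNA replication 40 were below control, 0 when adjusted over the list alone, with a median log2 fold change of -0.14 (camera adjusted p = 4.0e-06, and adjusted p = 0.378 with an estimated correlation). Fen1, a nuclease of DNA replication, was at 37.2 ± 1.2 against 43.3 ± 1.3 TPM, and the list median was -0.091 without Control 3. Of 42 genes of G2/M and mitosis 30 were above control, 0 when adjusted over the list alone, with a median of 0.06 (camera adjusted p = 0.0340, and adjusted p = 0.809 with an estimated correlation). This call was lost without Control 1, Control 3, EPZ5676 2 or EPZ5676 3, and the direction turned without Control 1 (median -0.0065, adjusted p = 0.713). Its median was 0.16 without Control 2 and 0.020 without EPZ5676 2. Cenpf and Aurka, mitotic proteins, had log2 fold changes of 0.28 ± 0.12 and 0.26 ± 0.11. Mki67, a marker of cycling cells, was at 119 ± 3 against 103 ± 20 TPM (log2 fold change 0.18 ± 0.12, edgeR adjusted p = 0.844). These libraries held whole explants, so the values do not separate epithelium from mesenchyme.

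Genes fixed in advance as anchors did not pass the threshold in this comparison. Dot1l itself (chromosome 10, 80755206 to 80795461, GRCm38) was at 20.8 ± 3.7 against 24.0 ± 5.6 TPM, with a log2 fold change of -0.20 ± 0.10 (edgeR adjusted p = 0.743). The list of DOT1L and its elongation partners had a median log2 fold change of 0.01, a mean of -0.0014 and a camera test pointing down (adjusted p = 0.921). The lung factor Nkx2-1 had a log2 fold change of 0.19 ± 0.10 and the epithelial adhesion gene Epcam of 0.22 ± 0.12. The tip marker Sox9 had 0.10 ± 0.25, the airway factor Sox2 0.16 ± 0.62, and the branching signal Fgf10 0.07 ± 0.29. Bmp4 had 0.26 ± 0.29, Shh -0.07 ± 0.20 and Etv5 -0.20 ± 0.23. Sftpc, a surfactant protein, was at 879 ± 499 against 542 ± 506 TPM, and the cell cycle inhibitor Cdkn1a had a log2 fold change of 0.15 ± 0.24. The direction turned with a library left out for 8 of these. Without Control 3 it turned for Sox9 (-0.16), Sox2 (-0.31) and Etv5 (0.0687), and without Control 1 for Fgf10 (-0.13), Shh (0.0155) and Cdkn1a (-0.035). Without EPZ5676 2 it turned for Fgf10 (-0.31), Bmp4 (-0.11), Shh (0.12), Sftpc (-0.0436) and Cdkn1a (-0.0196), and without EPZ5676 1 for Sox2 (-0.0263). An estimate within its error does not show that a gene was the same in both groups. Ptpn13, F13a1, Mdk, Fendrr and Trim71 were chosen after their values were seen, because both edgeR and DESeq2 ranked them near the top. Ptpn13 (log2 fold change 0.65 ± 0.10) and F13a1 (3.11 ± 0.50) were above control, and Mdk (-0.58 ± 0.10), the lung mesenchyme RNA Fendrr (-0.75 ± 0.13) and Trim71 (-1.31 ± 0.25) below it, with edgeR adjusted p-values between 0.131 and 0.179. Ddc, from the neuroendocrine list, was at 30.3 ± 5.3 against 15 ± 2.4 TPM, while the other 4 of the 5 tested members of that list were below control (list median -0.38, camera adjusted p = 0.921). Jag2, a Notch ligand, had a log2 fold change of 1.06 ± 0.22.

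**Figure D2:**
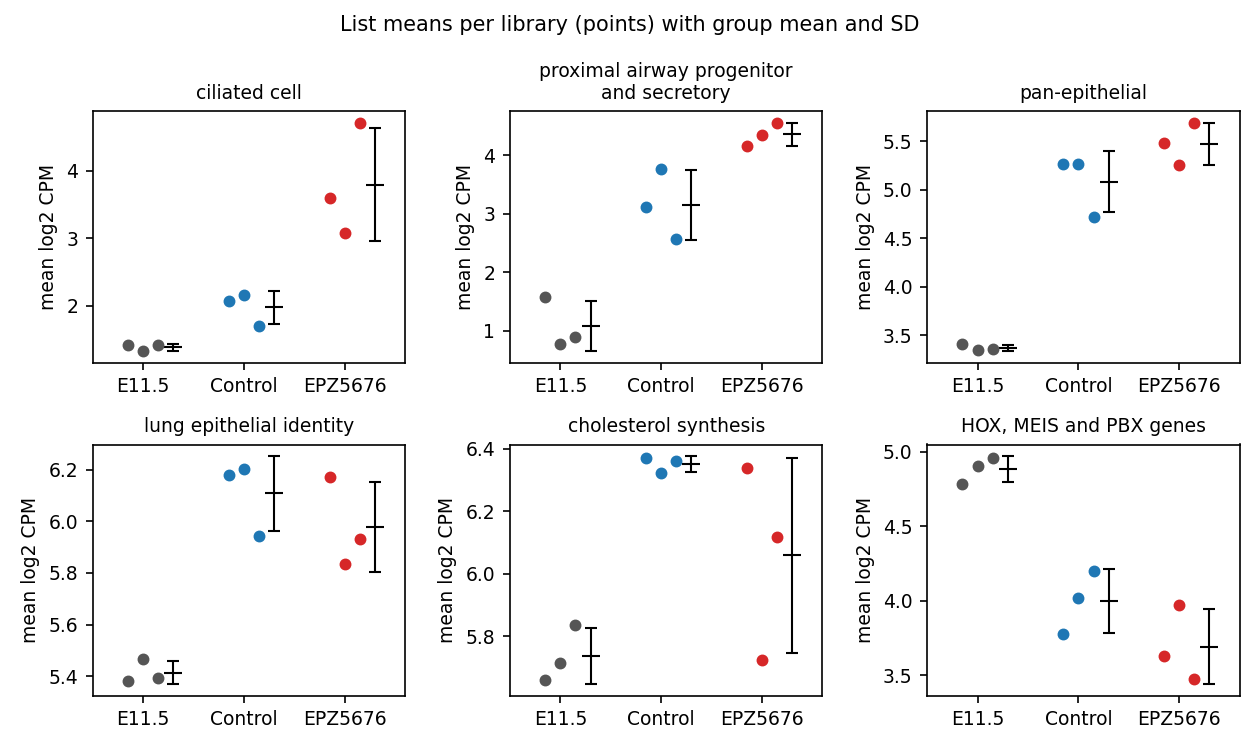
Mean log2 CPM over the tested members of 6 gene lists, with 1 point per library and the group mean ± SD beside the points (n = 3 per group). The ciliated cell list lies between 3.07 and 4.71 log2 CPM with EPZ5676 and between 1.70 and 2.16 log2 CPM in controls; the vertical axes differ between panels and do not start at 0.

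Of 51 gene lists 18 passed with camera at the preset correlation of 0.01, 9 up and 9 down, while 0 passed with an estimated correlation (5 at an unadjusted p under 0.05) and 0 with fry (8 at an unadjusted p under 0.05). Splitting the same 6 libraries in the other 9 ways gave 9 to 21 lists, in most ways 15 or more, so the real 18 lay inside their range.

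Control explants were next compared with fresh E11.5 lung. The explants were 72 h older as well as cultured, and no lung of matching age was sequenced, so changes after culture here include those of development. After 72 h the explants had gained transcripts of differentiated epithelium and macrophages and had lost those of blood vessels and red cells. Gpnmb, a glycoprotein of phagocytes (chromosome 6, 49036546 to 49070929, GRCm38), rose from 0.147 ± 0.057 to 480 ± 116 TPM (log2 fold change 11.96 ± 0.30, n = 3 per group, edgeR adjusted p = 8.0e-09). Sftpc rose from 13.4 ± 4.0 to 542 ± 506 TPM (log2 fold change 5.48 ± 1.09, edgeR adjusted p = 0.00915). Hbb-bh1, an embryonic globin, fell from 2713 ± 1313 to 6.04 ± 5.28 TPM (log2 fold change -8.76 ± 0.83, edgeR adjusted p = 3.1e-04). Cdkn1a rose from 3.55 ± 0.92 to 33.8 ± 6.0 TPM and Mki67 fell from 151 ± 9 to 103 ± 20 TPM.

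With edgeR's quasi-likelihood test 3202 of 15158 genes were higher and 2509 lower after culture, and 1589 and 666 of these changed at least 2-fold. For 51.4% of genes the 3 libraries of each group did not overlap, where chance gives 10%. Without E11.5 2 the test called 1666 lower genes and without E11.5 3 it called 1648. Limma-trend called 1970 higher and 2105 lower genes on log2(TPM + 1), and 2021 and 2006 on log2(TPM + 0.1).

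Among the largest rises were further genes of phagocytes and of matrix. Spp1, a secreted phosphoprotein, had 14524 counts after culture and 3 counts in fresh lung, a ratio of 4136 with a 95% counting interval (exact binomial) of 1415 to 20056. Lgals3, a galectin abundant in macrophages, rose from 1.71 ± 1.12 to 192 ± 63 TPM. Of the genes with 0 counts in all 3 fresh libraries, Aspn, a matrix proteoglycan, was at least 227-fold higher, Agtr2, an angiotensin receptor, at least 202.5-fold, and Atp6v0d2, a proton pump subunit of osteoclasts and macrophages, at least 126-fold. Lypd2 was at least 24.8-fold higher, Cd300lb at least 21.1-fold and Dpt at least 19.7-fold, against a floor of 3 counts summed over the fresh group. Among the largest falls, Hoxb1 was at least 28.9-fold lower, Slfn14 at least 28.5-fold, Zfp663 at least 23.0-fold and the pseudogene Hmgb1-ps2, which may share reads with Hmgb1 and is uncertain, at least 18.7-fold. The embryonic globin Hba-x fell from 2993 ± 897 to 14 ± 7.8 TPM, and reads of the globin genes can be split between near-identical copies. Aplnr, the apelin receptor of vessels, fell from 26.6 ± 4.2 to 0.523 ± 0.855 TPM. Ppbp, Lmx1a and Lin28a each had 1 count left after culture, against 137, 100 and 83 counts in fresh lung.

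Epithelial genes rose broadly. All 28 pan-epithelial genes were higher, 27 of them past the threshold over all genes and 28 adjusted over the list alone, with a median log2 fold change of 1.59 (camera adjusted p = 6.3e-13, and adjusted p = 0.252 with an estimated correlation). Cldn3, a tight junction protein, rose from 6.13 ± 1.07 to 45.2 ± 11.7 TPM, Krt19 from 9.09 ± 2.41 to 58.6 ± 18.5 TPM, and Epcam from 79.8 ± 3.6 to 187 ± 47 TPM. Of 13 alveolar type 2 genes 9 rose, 10 adjusted over the list alone, with a median of 2.36 (camera adjusted p = 4.1e-05, and adjusted p = 0.212 with an estimated correlation). Lamp3, a lamellar body protein, rose from 0.17 ± 0.17 to 6.61 ± 0.34 TPM. Of 14 alveolar type 1 genes 11 rose, 12 adjusted over the list alone, with a median of 2.32 (camera adjusted p = 2.7e-05, and adjusted p = 0.252 with an estimated correlation). Hopx, a transcription cofactor of these cells, rose from 2.28 ± 0.16 to 16.6 ± 8.2 TPM and Clic5 had a log2 fold change of 3.07 ± 0.35. Of 13 lung epithelial identity genes 9 rose and 1 fell, with the same counts adjusted over the list alone and a median of 0.84 (camera adjusted p = 0.00339, and adjusted p = 0.305 with an estimated correlation). In this list Nkx2-1 rose from 35.5 ± 4.7 to 75.1 ± 3.3 TPM and Shh from 16.4 ± 3.0 to 24.9 ± 6.6 TPM. The call of Shh was lost in 5 of 6 edgeR fits without a library, with adjusted p up to 0.122 without E11.5 1. Of 11 proximal airway genes 7 rose and 1 fell, with the same counts adjusted over the list alone and a median of 2.24 (camera adjusted p = 0.0182, and adjusted p = 0.373 with an estimated correlation). Klf5 rose from 1.19 ± 0.60 to 14.7 ± 6.6 TPM, and Scgb3a2 had 241 counts after culture and 2 before it. The proximal airway median was 3.55 without E11.5 1.

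The ciliated cell list, by contrast, did not pass in this comparison. Of its 14 members 4 rose and 1 fell, with the same counts adjusted over the list alone and a median log2 fold change of 0.60 (camera adjusted p = 0.574). Ccdc40, which works with Ccdc39, fell from 4.14 ± 0.41 to 1.03 ± 0.60 TPM, and Mcidas, a driver of the multiciliated fate, had 43 counts after culture and 2 before it. With a library left out edgeR no longer called Ccdc40 in 3 of 6 fits (adjusted p up to 0.0559) and Mcidas in 5 of 6 (adjusted p up to 0.0923). The distal tip list did not pass either (camera adjusted p = 0.349): 2 of 13 members rose and 5 fell, or 3 and 5 adjusted over the list alone. Its median was 0.14, while its mean was -0.47 and the test pointed down. Lin28b and Hmga2, regulators of early progenitors, fell by 3.26 ± 0.17 and 2.94 ± 0.21 on the log2 scale.

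Macrophage genes rose while vascular and red cell genes fell. Of 22 macrophage and leukocyte genes 19 rose and 1 fell, with the same counts adjusted over the list alone and a median log2 fold change of 2.01 (camera adjusted p = 2.8e-07, and adjusted p = 0.252 with an estimated correlation). Lyz2, lysozyme, rose from 3.61 ± 1.37 to 443 ± 61 TPM and Trem2, a phagocyte receptor, from 1.02 ± 0.67 to 26.3 ± 4.1 TPM. All 23 endothelial genes were lower, 20 past the threshold and 22 adjusted over the list alone, with a median of -2.14 (camera adjusted p = 1.2e-10, and adjusted p = 0.337 with an estimated correlation). Tek, an angiopoietin receptor, fell from 15 ± 1.2 to 1.60 ± 1.20 TPM. Of 19 erythroid genes 17 fell, 18 adjusted over the list alone, with a median of -4.05 (camera adjusted p = 2.3e-09, and adjusted p = 0.252 with an estimated correlation). Alas2, the red cell enzyme of haem synthesis, fell from 49.0 ± 7.7 to 1.44 ± 1.41 TPM. The erythroid list mean was 2.82 log2 CPM in Control 1 and 0.73 and 0.56 log2 CPM in Control 2 and Control 3, and the list median was -6.81 without Control 1. Globin genes held 0.601% to 0.818% of the counts in the fresh libraries and at most 0.0366% in the cultured ones.

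Genes of growth and division fell. Of 34 ribosome biogenesis and MYC target genes 25 fell, 30 adjusted over the list alone, with a median log2 fold change of -0.52 (camera adjusted p = 1.2e-10, and adjusted p = 0.212 with an estimated correlation). Ncl, nucleolin, fell from 954 ± 60 to 463 ± 68 TPM and Odc1, the first enzyme of polyamine synthesis, from 277 ± 13 to 92.2 ± 36.4 TPM. Of 42 G2/M genes 26 fell and 1 rose, or 29 and 1 adjusted over the list alone, with a median of -0.40 (camera adjusted p = 7.1e-08, and adjusted p = 0.366 with an estimated correlation). Bub1b and Birc5, both of the mitotic spindle machinery, fell by 0.65 ± 0.10 and 0.61 ± 0.11 on the log2 scale. Of 42 G1/S genes 22 fell and 1 rose, with the same counts adjusted over the list alone and a median of -0.33 (camera adjusted p = 2.4e-05, and adjusted p = 0.252 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell from 192 ± 24 to 87.7 ± 18.2 TPM and Mcm10 by 0.60 ± 0.13 on the log2 scale. Of 22 HOX, MEIS and PBX genes 12 fell, also 12 adjusted over the list alone, with a median of -0.67 (camera adjusted p = 9.0e-06, and adjusted p = 0.252 with an estimated correlation). Hoxc4 fell from 12.7 ± 2.5 to 2.74 ± 0.99 TPM. With Hoxb1 at its bound the list's median was again -0.67.

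Stress genes rose. Of 26 p53 targets 18 rose and 1 fell, or 19 and 1 adjusted over the list alone, with a median log2 fold change of 1.12, also with Gdf15 at its bound (camera adjusted p = 2.1e-06, and adjusted p = 0.238 with an estimated correlation). Gdf15, a stress cytokine, was at least 12.5-fold higher, and Eda2r, a receptor induced by p53, rose from 1.21 ± 0.17 to 12.9 ± 5.0 TPM. Of 24 genes of the integrated stress and unfolded protein response 16 rose, also 16 adjusted over the list alone, with a median of 0.92 (camera adjusted p = 8.4e-06, and adjusted p = 0.252 with an estimated correlation). Chac1 had 211 counts after culture and 1 before it, and Trib3 had a log2 fold change of 2.81 ± 0.59. Of 21 immediate early and heat shock genes 14 rose and 1 fell, or 15 and 1 adjusted over the list alone, with a median of 1.16 (camera adjusted p = 3.6e-05, and adjusted p = 0.212 with an estimated correlation). Egr1 rose from 4.04 ± 1.07 to 39.98 ± 16.6 TPM and Fos from 2.12 ± 2.17 to 13.8 ± 2.0 TPM.

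Matrix and lipid genes rose as well. Of 30 basement membrane and matrix genes 20 rose and 1 fell, or 21 and 1 adjusted over the list alone, with a median log2 fold change of 0.58 (camera adjusted p = 5.5e-07, and adjusted p = 0.212 with an estimated correlation). Eln, elastin, rose from 12.7 ± 9.0 to 159 ± 35 TPM and Loxl1, which crosslinks it, from 3.87 ± 0.89 to 21.8 ± 8.8 TPM. Of 25 mesenchyme and fibroblast genes 13 rose and 2 fell, or 13 and 3 adjusted over the list alone, with a median of 0.63 (camera adjusted p = 0.00200, and adjusted p = 0.366 with an estimated correlation). Col6a3 rose from 5.88 ± 3.36 to 93.0 ± 19 TPM and Dcn, decorin, from 16.3 ± 7.5 to 193 ± 103 TPM. Of 25 cholesterol synthesis genes 15 rose, 19 adjusted over the list alone, with a median of 0.64 (camera adjusted p = 4.1e-05, and adjusted p = 0.402 with an estimated correlation). Of 16 fatty acid synthesis genes 10 rose, also 10 adjusted over the list alone, with a median of 0.57 (camera adjusted p = 3.2e-04, and adjusted p = 0.299 with an estimated correlation). Pparg rose from 0.41 ± 0.46 to 4.66 ± 1.56 TPM and Srebf1 from 27.1 ± 6.1 to 52.3 ± 10.8 TPM. Of 30 hypoxia and glycolysis genes 15 fell and 4 rose, or 15 and 5 adjusted over the list alone, with a median of -0.40 (camera adjusted p = 6.3e-04, and adjusted p = 0.329 with an estimated correlation). Eno1, enolase, fell from 259 ± 28 to 87.2 ± 5.6 TPM and Slc2a3, a glucose transporter, from 25.8 ± 8.4 to 8.92 ± 1.24 TPM. Slc2a3 lost its call in 4 of 6 edgeR fits without a library, with adjusted p up to 0.0778.

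**Figure D3:**
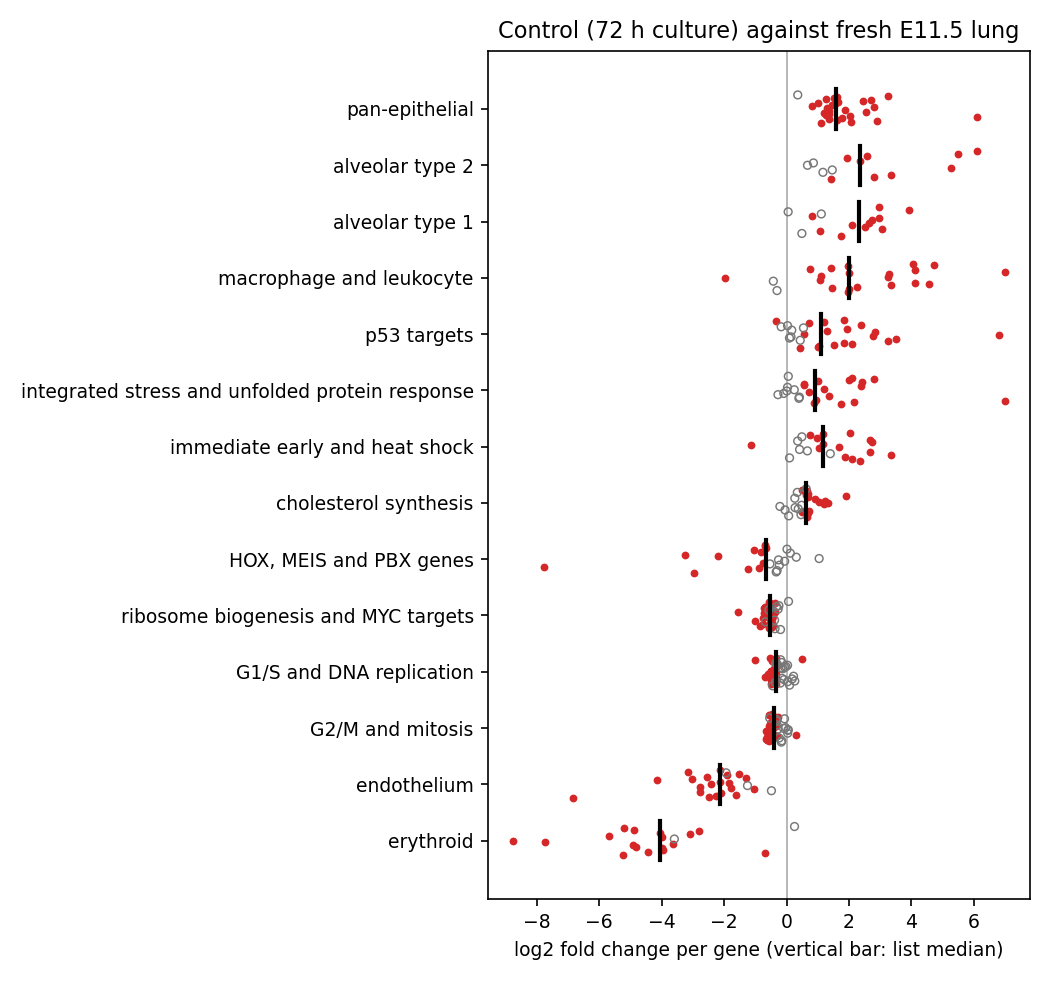
Log2 fold change of each tested member of 14 gene lists in control explants against fresh E11.5 lung (n = 3 per group). Filled red points passed an adjusted p of 0.05 over all genes with edgeR, open grey points did not, and the vertical bar is the list median, from -4.05 for erythroid genes to 2.36 for alveolar type 2 genes.

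Of the anchors not yet given, Dot1l was at 24.0 ± 5.6 TPM after culture and 22.5 ± 1.1 TPM before it (log2 fold change 0.16 ± 0.10, edgeR adjusted p = 0.206). Sox9 (0.14 ± 0.26), Sox2 (1.45 ± 0.67), Fgf10 (0.62 ± 0.30), Bmp4 (0.40 ± 0.30) and Etv5 (0.18 ± 0.23) did not pass the threshold, with log2 fold changes in parentheses. Sox9 turned without Control 1 (-0.10), and Etv5 without Control 3 (-0.0854) and with limma-trend on both TPM scales. Without Control 3, Sox2 had a log2 fold change of 1.93 and passed with edgeR (adjusted p = 0.00273). Of 51 lists 27 passed with camera at the preset correlation, 19 up and 8 down, while 0 passed with an estimated correlation (7 at an unadjusted p under 0.05) and 30 with fry, which does not compare a list with other genes.

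EPZ5676 explants were also compared with fresh lung, which shows culture, development and inhibitor together. Spp1 rose to 835 ± 183 TPM, Gpnmb rose from 0.147 ± 0.057 to 492 ± 118 TPM (log2 fold change 11.98 ± 0.30, n = 3 per group, edgeR adjusted p = 7.9e-09), and Aspn was at least 297-fold higher. Among the largest falls were the red cell genes Kel, at least 115-fold lower, Hbb-bh1, from 2713 ± 1313 to 3.57 ± 3.34 TPM, and Slc4a1, the anion exchanger, from 51.8 ± 10.7 to 0.127 ± 0.10 TPM. With edgeR 3350 genes were higher and 2712 lower.

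Both comparisons against fresh lung shared 2755 higher and 2080 lower genes. Independent lists of these lengths would share 707.7 and 448.9, and 5 simulations with the same fresh libraries and no effect of EPZ5676 shared 2582.6 and 1939.6 on average. In opposite directions there were 0 genes higher after control culture and lower with EPZ5676, and 3 the other way round. The simulations gave both cultured groups the same mean, apart from that of fresh lung. Most of the sharing thus arose without an effect of EPZ5676. The simulations do not separate the common change against fresh lung from the shared fresh libraries. Across genes, the covariance of the EPZ5676 effect with the culture effect (control explants minus fresh lung) was 0.0086 (correlation 0.0249), where genes are not independent replicates. The sign turned on log2(TPM + 1), at -0.0331, without Control 1, 2 or 3 (-0.0547, -0.0441 and -0.0095) and without EPZ5676 3 (-0.0048). These effects share the control libraries with opposite sign, and 100 simulations without an effect of EPZ5676 gave a covariance of -0.0547 on average, with a highest of -0.0457. The correlation was -0.168 on average in those simulations. The spread of the controls gives a covariance of -0.0771 over all libraries. It gives -0.119, -0.153 and -0.0947 without Control 1, 2 and 3, and -0.0814 without EPZ5676 3. With the controls parted so that no library entered both effects, the covariance was 0.0588 to 0.115 over the 6 ways to part them. On log2(TPM + 1) it was 0.0391 to 0.0676 over these ways.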

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

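The newer quasi-likelihood fit and the Xist covariate were chosen after the results were seen. EPZ5676 against control gave 0 higher and 0 lower genes, against 88 and 16 with DESeq2 and 67 and 9 without a filter. It gave 1 and 0 on log2(TPM + 0.1) and 0 to 26 higher and 0 to 1 lower with a library left out, with 0 and 0 under the other settings except the block, both added ones included. Same-numbered control and EPZ5676 libraries deviated with correlations of 0.457, 0.0789 and -0.0468, so the numbers were not taken to pair all of them. Control 1 and EPZ5676 1 were still more alike (log2 CPM correlation 0.973) than any libraries of the same treatment (highest 0.971). Whether these libraries share a batch was not tested, and the labels name none. The replicate block gave 1 higher gene. The single calls were Lrrc23 (block), Fam183b (TPM), Ahcy (without Control 2) and Fam220a (without EPZ5676 3), named after their values were seen. Control against E11.5 gave 1970 higher and 2105 lower genes on log2(TPM + 1), 2021 and 2006 on log2(TPM + 0.1), against 3202 and 2509, and 1589 higher and 666 lower with a 2-fold limit. Leaving out a library gave 2271 to 3200 higher and 1648 to 2472 lower. EPZ5676 against E11.5 gave 1821 and 694 with the 2-fold limit. Called lists fell from 18 to 0 with an estimated correlation or fry for EPZ5676 against control, and from 27 to 0 with an estimated correlation for culture, with 14 to 22 and 25 to 29 over left-out libraries. The covariance was -0.0331 on log2(TPM + 1) and -0.0547 to 0.0167 over left-out libraries (-0.0547, -0.0441 and -0.0095 without Control 1, 2 and 3, -0.0048 without EPZ5676 3). The value that the spread of the controls gives moved too, from -0.153 to -0.0802 over left-out libraries. Directions also turned for genes not called. For EPZ5676 against control with a library left out, log2 fold changes ranged from -0.16 to 0.35 for Sox9 and from -0.31 to 0.59 for Sox2 (lowest without Control 3), from -0.31 to 0.33 for Fgf10, -0.11 to 0.53 for Bmp4 and -0.0436 to 1.82 for Sftpc (lowest without EPZ5676 2), from -0.20 to 0.12 for Shh (highest without EPZ5676 2), from -0.43 to 0.0687 for Etv5 (highest without Control 3) and from -0.035 to 0.39 for Cdkn1a (lowest without Control 1). For culture they ranged from -0.10 (without Control 1) to 0.40 for Sox9 and from -0.0854 (without Control 3) to 0.41 for Etv5, which was -0.0278 on log2(TPM + 1) and -0.0284 on log2(TPM + 0.1). The adjusted p of the G2/M list ranged from 1.2e-06 to 0.713 for EPZ5676, and the list turned without Control 1. Except for the DESeq2 calls, the cause was not tested for these changes with the setting.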

Other observations

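All tests of explanations below were chosen only after the result was seen, including the counts of splits.

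In control explants against fresh lung, which differ in age as well as culture, genes of retinoic acid handling and of imprinted loci changed in both directions. Of 14 retinoic acid genes 5 rose and 4 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.410, and with fry, which does not compare a list with other genes, adjusted p = 0.00162, down). Stra6, a retinol transporter, fell from 19.5 ± 2.4 to 2.72 ± 0.67 TPM and Crabp2, a retinoic acid carrier, from 85.2 ± 9.97 to 14.4 ± 1.2 TPM. Of 23 imprinted genes 4 rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.398, fry adjusted p = 0.0928). Peg10 fell from 110 ± 21 to 29.6 ± 14.5 TPM and Mest from 811 ± 46 to 256 ± 81 TPM, while Dlk1 rose from 197 ± 27 to 566 ± 119 TPM. The cytosolic ribosomal protein list rose (median log2 fold change 0.44, and 0.21 without Control 3), with 21 of 50 members higher over all genes and also adjusted over the list alone (camera adjusted p = 2.8e-05, and adjusted p = 0.637 with an estimated correlation), while the ribosome biogenesis list fell. The mitochondrially encoded list, with 4 of 13 members higher (also 4 adjusted over the list alone), passed with camera adjusted p = 0.0182 (adjusted p = 0.637 with an estimated correlation), a call lost without E11.5 2 or Control 3.

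Signalling and other lists passed in this comparison too. Of 23 FGF signalling genes 11 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0182, and adjusted p = 0.402 with an estimated correlation). Of 18 apoptosis genes 10 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0182, and adjusted p = 0.252 with an estimated correlation). Of 6 CDK inhibitors 4 rose, also 4 adjusted over the list alone (camera adjusted p = 0.0298, and adjusted p = 0.252 with an estimated correlation). Of 16 smooth muscle genes 5 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0384, and adjusted p = 0.637 with an estimated correlation), a call lost without Control 1 or Control 2 (median 0.59, and 0.16 without Control 1 and 0.96 without Control 3). Of 5 foregut and stomach genes 3 fell and 1 rose, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0344, and adjusted p = 0.412 with an estimated correlation), a call lost without Control 2 or Control 3.

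Against control, EPZ5676 explants had 16 of 23 imprinted genes lower in mean (median log2 fold change -0.13, camera adjusted p = 0.0106, and adjusted p = 0.482 with an estimated correlation), a call lost without Control 1 or EPZ5676 3. Control 1 held more liver, heart muscle and cartilage transcripts than the other controls. Of 12 genes of epithelial-mesenchymal transition 10 were lower in mean (median -0.18, camera adjusted p = 0.00410, and adjusted p = 0.498 with an estimated correlation), a call lost without Control 1 (median -0.045, adjusted p = 0.265) or EPZ5676 3, and the median was -0.28 without Control 3.

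The first pattern is the higher ciliated cell genes with EPZ5676. A larger share of epithelium would raise pan-epithelial genes as much, but ciliated minus pan-epithelial means differed by 1.43 log2 units between the groups, against a pooled SD of 0.447 between libraries. The lowest median with a library left out was 1.33 (without EPZ5676 3, against 1.90 over all), which argues against a single library as the whole cause. With the Xist level as a covariate the median was 1.88, but that fit takes the same slope in all groups. Libraries with high Xist had the higher list means among controls (2.07 and 2.16 against 1.70 log2 CPM). With EPZ5676 the library with high Xist had the lowest (3.07 against 3.60 and 4.71 log2 CPM). Opposite slopes can cancel, so the covariate cannot decide on the sex of the embryos. The EPZ5676 minus control difference in list mean was 0.956 among libraries with high Xist (1 EPZ5676, 2 controls) and 2.45 among those with low Xist (2 and 1). Of the 10 splits of the 6 libraries 1 gave a median as large, the real value being 1.82 and the highest other 1.16, and 10 splits are too few for a share under 0.05. A candidate explanation that stays open is more multiciliated cells in treated explants, or more transcripts per such cell, and whole-explant RNA cannot separate these.

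The second pattern is the 0 genes called by edgeR against 104 by DESeq2 for EPZ5676 against control. Weaker control of chance calls by DESeq2 may account for part of it, since on simulated data 20.99% of its calls were false (34 of 162, 95% binomial interval 14.99% to 28.1%), against 7.26% with edgeR. That was a single simulated data set of the filtered genes, drawn with edgeR's own estimates of the spread, while the real DESeq2 fit was not filtered. There edgeR made 124 calls, so the simulation does not reproduce 0 against 104. Of the 10 splits, too few for a share under 0.05, 4 gave at least the real 104 calls, the real split included. The highest other was several times larger, at 397 for Control 2, Control 3 and EPZ5676 2 against the rest, where edgeR called 3. So DESeq2 also made many calls where the groups mixed treatments. The mixed splits with 397, 155 and 113 calls all kept Control 1 and EPZ5676 1 in the same group, as did that with 15. The other mixed splits, which parted these libraries, gave 0 to 6 calls, while the real split, which also parts them, gave 104. Control 1 and EPZ5676 1 were the most alike of the cultured libraries (log2 CPM correlation 0.973). The calls of the mixed splits need not be chance calls, and their cause was not tested. Untested genes are not the main part, since edgeR did not test 23.1% of the DESeq2 calls (24 of 104) and gave the other 80 adjusted p-values from 0.131 to 0.390, but the filter as a whole stays open, since edgeR without it called 53.8% of them (56 of 104, 40 of these tested in the main fit). Of the 104 calls 10 belonged to the ciliated cell list, which has only 18 members. Calls outside the list included genes with the family names of its members, such as Dnah6, Dnah10 and Rsph4a, chosen after their values were seen. Cilia genes beyond the list were not counted, so 10 is not their full share of the calls.

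The third pattern is the covariance of the EPZ5676 effect with the culture effect, 0.0086, above the negative value expected from the shared controls. Shared controls are argued against, with limits. With the controls parted so that none entered both effects, they would give about 0, while the lowest of 6 covariances, which share libraries, was 0.0588. Their mean was 0.0855, nearly the unparted covariance less its value from the control spread (0.0857). The parting is thus the same quantity in another form and no separate support. The jackknife SE over the libraries of each group was 0.0283. It is the SE of the unparted covariance less its value from the control spread, and is rough with 3 libraries a group. A single parting uses fewer controls and is less precise, and its SE was not estimated. Moreover, 2 other criteria had been tried first and withdrawn. A single library is argued against, since the difference from the value that the spread of the controls gives (-0.0771 over all) was at least 0.0644 with any library left out. Of 20 labelings 1 was as high (highest other -0.0148), and 20 are too few for a share under 0.05. Whether EPZ5676 pushed explants further along the changes of culture and development stays open.

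For the number of genes called by edgeR, the real 0 for EPZ5676 against control (highest other 4) is met by all 10 of 10 splits whatever they hold, so this count tests nothing. For control against E11.5, 1 of 10 splits gave the real 5711 (highest other 0), and for EPZ5676 against E11.5, 1 of 10 gave 6062 (highest other 0). The other splits mixed fresh and cultured libraries in each group, so their large difference widened the spread there. These values of 0 therefore do not measure chance calls. For gene lists, 3 of 10 splits gave at least the real 18 for EPZ5676 against control (highest other 21), and 1 of 10 gave 27 for control against E11.5 (highest other 22). For these 4 counts 10 splits are too few for a share under 0.05.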
